A study of Rattus norvegicus with 18 samples.

How the data were processed

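DNA methylation was measured with the HELP assay in liver and in perinephric visceral fat of male F344*BN rats aged 3 or 18 months. HELP compares 2 digests of the same genomic DNA. HpaII cleaves CCGG only where the site is unmethylated, while its isoschizomer MspI cleaves the site in either state. Short fragments from both digests are amplified, labelled with different dyes and hybridised together to an oligonucleotide array whose probes lie in HpaII fragments. A high HpaII over MspI ratio therefore marks a fragment whose flanking CCGG sites were little methylated, and a low ratio marks a methylated one.

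Each of the 18 arrays came with probe intensity values for 2 channels, which the authors deposited as scanner output of the NimbleScan software. Per the file headers, 11 arrays were extracted with NimbleScan 2.2.28 and 7 with version 2.3.16. Per the labels, HpaII was in Cy5, read at 635 nm, and MspI in Cy3, read at 532 nm, on every array, with no dye swap. A value table of log2 ratios per fragment was also deposited by the authors, and the submitters' processing notes name RMA, with neither version nor role. Each column of that table followed the scanner log2 ratios of its own array, with Pearson correlations across fragments between 0.985 and 0.998, so its direction and log2 scale were settled from the values. Its columns were not centred on 0, and their medians were -0.97 in young liver, -1.20 in old liver, -1.05 in young fat and -1.11 in old fat. Sorted columns of the same group differed by less than 0.001 at every rank, so the columns had been made equal in distribution within each group and not between groups. What background step or probe summary made it is not given in the sources used here. For that reason the scanner intensities are the main source and the value table is an alternative.

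From the intensities, each channel of a fragment was summarised as the 20% trimmed mean of its perfect-match probes. The log2 ratio of HpaII over MspI was then centred on the median of each array over the fragments tested. No loess or quantile step was applied, because many fragments may differ in one direction between tissues. Background was taken from the random-sequence probes of each array, as their median plus 2.5 MAD in the channel concerned. A fragment was tested where its MspI signal exceeded this level in at least 3 arrays of each group, which left 23063 fragments of 38102. The share of those fragments whose HpaII signal did not exceed background was taken per array as a measure of methylation that does not use the ratio.

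Groups follow the sample titles, with 6 young livers, 5 old livers, 4 young fat samples and 3 old fat samples. Fragments were compared in limma (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05) with 4 group means over all 18 arrays. The contrasts were old against young liver, old against young fat, fat against liver at each age, and the difference between the age effects of fat and liver. In the tissue contrasts a positive difference means less methylation in fat. Array shares were compared by exact permutation of the group labels. The software was R 4.3.3 with the packages limma 3.58.1 and data.table (version 1.17.8). On simulated data with 200 changed fragments per size, log2 changes of 1 were recovered in 85.5% of cases for age in liver, 57.5% for age in fat, 75% for tissue in young animals and 63% for tissue in old animals. The design, the alternatives and the rule for naming fragments were fixed before the data were examined, except where a test is said to have been chosen later.

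Per comparison, the named fragments are the 5 with the largest rise and the 5 with the largest fall among those past the threshold whose values did not overlap between the groups. These were 321 of 354 for age in liver, 3716 of 5562 for tissue in young and 7533 of 8444 for tissue in old animals. Single fragments called largest are the largest among these. For the difference between age effects, overlap was not considered. Where fewer than 5 fragments passed, the 10 with the smallest p are given. A region is a series of at least 3 called fragments of one direction with gaps of at most 2000 bp and no uncalled or opposite fragment between them. Coordinates are as the probe names give them. Fragment names begin with RN34, and the assembly is otherwise not given in the sources used here. No annotation on these coordinates was used, so fragments are named by position. The gene lists and cell-type marker sets that had been fixed for testing were not run, and whether a fragment lies in a gene, exon or promoter is not analysed here.

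The alternatives were loess within arrays, quantile normalization between arrays or within bins of fragment length, normexp background correction, and the median of probes. Others were a stricter or no MspI filter, the value table, array weights, trended and robust eBayes, only the arrays compared, and a minimum log2 difference of 1. Serial-number series, replicate number and the date in the file header were used as blocks, and each sample was left out in turn. Date as a block, comparisons within dates, leaving out 5 dim arrays, an MspI filter on the compared groups alone and renewed quantile normalization of the value table were chosen after seeing the data.

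The number of arrays limits the precision of every value. The median standard error of a group difference was 0.18 log2 units for age in liver, 0.23 for age in fat, 0.20 for tissue in young animals and 0.22 for tissue in old animals. MspI signal lay above background for 61.1% to 93.2% of fragments per array. The 5 arrays under 75% were young liver 1, young liver 4, young liver 5, young fat 1 and old fat 3. The labels do not say that each sample is a separate animal, so p-values measure the spread between these samples, which may in part be technical.

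Dates come from the file headers and serial-number series from the leading characters of the array numbers, and both are coded here by letters. Whether a header date marks scanning or a later step was not established. Whether a series marks a manufacturing or processing batch was not established either. Arrays of dates A, B and C were all extracted with NimbleScan 2.2.28, and those of dates D, E and F with 2.3.16. All old livers thus have version 2.2.28 and all young fat samples 2.3.16. Date A holds 2 young and 3 old livers, and date B holds 2 young and 2 old livers. Date D holds 2 young livers, 2 young fat samples and 1 old fat sample. Date C holds 2 old fat samples, and dates E and F hold 1 young fat sample each. Livers and fat of old animals never share a date. Series E holds young livers 1, 2 and 4, old livers 1 and 2 and young fat 1. Old livers 3 to 5 are alone in series B, young fat 2 and 3 in D, young fat 4 in A and old fat 2 in C. Series F holds young livers 5 and 6 and old fat 1, and series G holds young liver 3 and old fat 3. No series holds both ages of fat, or liver and fat of old animals, so blocked values there are linked through young livers.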

Results

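Liver and perinephric visceral fat of young (3 months) and old (18 months) male F344*BN rats were compared, to ask where DNA methylation differs with age and whether the difference depends on the tissue. Methylation was read as the log2 ratio of HpaII over MspI signal per fragment, so that a higher value means less methylation. The data comprise 18 arrays, of 6 young livers, 5 old livers, 4 young fat samples and 3 old fat samples, and 23063 fragments were tested. The tissue of origin set the arrays apart more than age did. The median correlation of log2 ratios across fragments was 0.97 between arrays of the same group, 0.97 between ages of the same tissue and 0.88 between tissues of the same age. MspI signal exceeded background for 80.2% ± 11.4 of all fragments on the array in young liver (SD, n = 6), 90.6% ± 2.94 in old liver (SD, n = 5), 87.9% ± 9.01 in young fat (SD, n = 4) and 78.7% ± 15.7 in old fat (SD, n = 3). In all groups short fragments had higher ratios than long ones, a difference in ratio that was not separated from effects of length on amplification. In young liver the median log2 ratio was 0.85 ± 0.26 (SD, n = 6) over fragments with a last probe at 271 bp or less and -0.71 ± 0.22 over those beyond 816 bp. The ratio fell from each length class to the next on 16 of the 18 arrays. Fragments of the mitochondrial genome had high ratios throughout, with means of 2.24 ± 0.26 in young liver, 2.16 ± 0.41 in old liver, 2.24 ± 0.26 in young fat and 2.24 ± 0.21 in old fat.

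**Figure D1:**
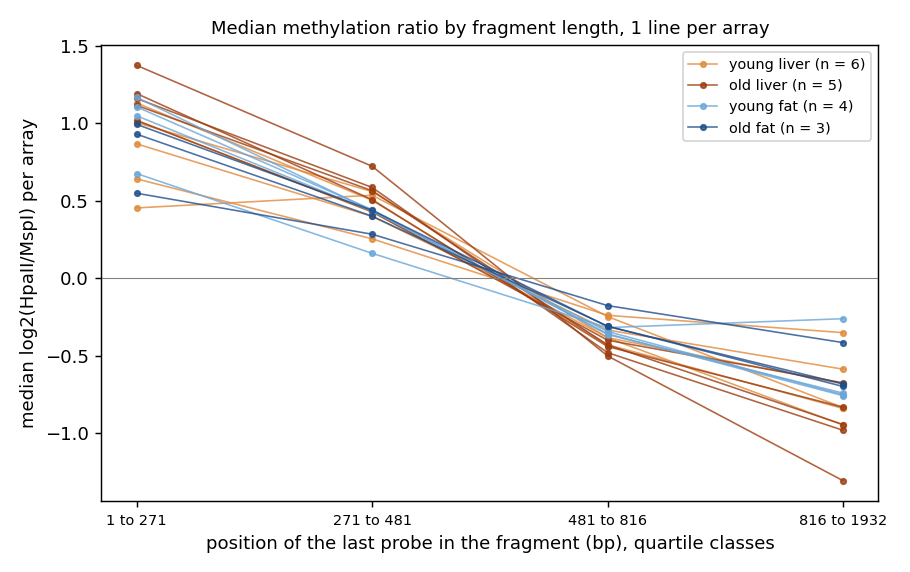
Median log2(HpaII/MspI) of each array in 4 classes of fragment length (bp to the last probe), with 1 line per array coloured by group. The shortest class had the highest mean in every group and the longest class the lowest.

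Old liver was less methylated than young liver at 231 fragments and more methylated at 123, together 354 fragments or 1.53% of those tested (limma, adjusted p under 0.05). The largest loss of methylation was on chromosome 11 from 37599226 to 37599556. There the log2 ratio rose from -1.06 ± 0.37 in young liver (SD, n = 6) to 1.20 ± 0.15 in old liver (SD, n = 5), a 4.76-fold higher HpaII over MspI ratio (difference 2.25, SE 0.26, limma adjusted p = 9.95e-05). HpaII signal was above background there on 5 of 6 young livers. The fragment at 63935957 to 63936937 on chromosome 10 rose from -0.14 ± 0.24 to 1.82 ± 0.39, a 3.88-fold higher ratio (limma adjusted p = 1.03e-05). The largest gain of methylation was on chromosome 14 from 19113845 to 19114345, where the log2 ratio fell from 0.12 ± 0.27 to -1.83 ± 0.20 (difference -1.94, SE 0.15, limma adjusted p = 1.21e-06). The neighbouring fragment, from 19114497 to 19115482, fell from 0.52 ± 0.14 to -0.80 ± 0.42.

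Among the other named fragments, 3 lost methylation. On chromosome 13 from 80220535 to 80220705 the difference was 1.88, on chromosome 2 from 203536064 to 203536444 it was 1.79, and on chromosome 1 from 213127353 to 213127583 it was 1.64. A further 3 gained methylation. The difference was -1.40 on chromosome 2 from 2892808 to 2893687, -1.32 on chromosome 1 from 42226795 to 42227859, and -1.25 on chromosome 11 from 76472629 to 76473246. Their limma adjusted p-values lay between 2.81e-05 and 0.00265. Over all 354 fragments the median difference was 0.86 for losses of methylation and -0.71 for gains.

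**Figure D2:**
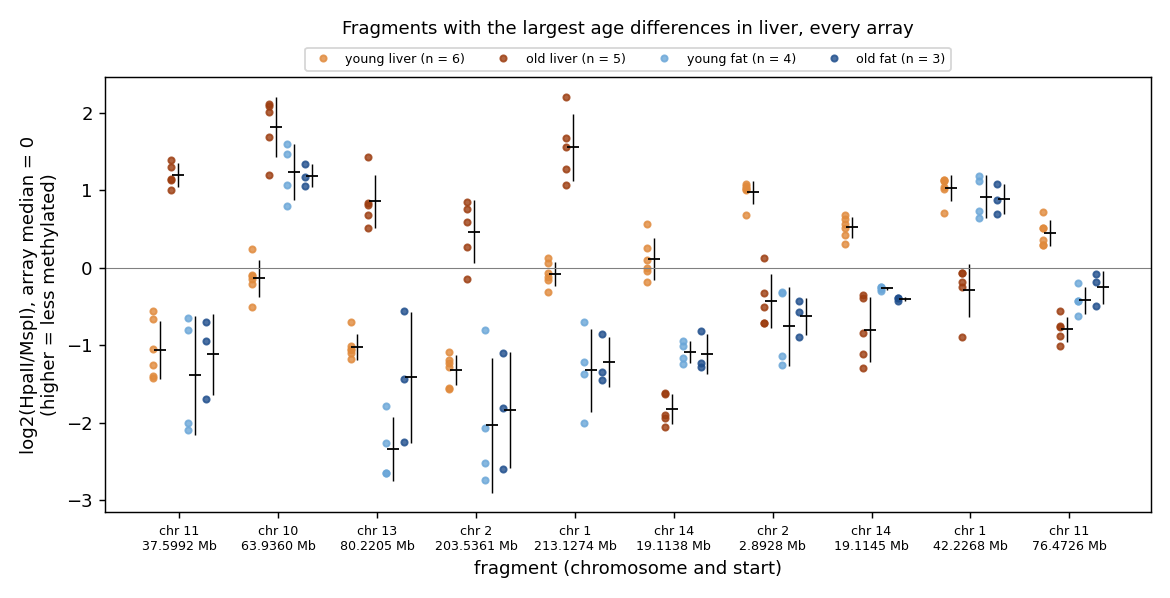
Log2(HpaII/MspI) on every array (points, coloured by group) for the 10 named liver fragments, with group mean ± SD in black. Old livers lay above all young livers at the 5 fragments on the left and below all of them at the 5 on the right.

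Called fragments lay side by side in 6 regions, 5 of them less methylated in old liver and 1 more methylated. The longest held 4 fragments on chromosome 7 between 135712711 and 135714834. Its mean log2 ratio was -0.10 ± 0.21 in young liver and 1.10 ± 0.10 in old liver, a 2.3-fold higher ratio, against -0.76 ± 0.16 in young fat and -0.46 ± 0.20 in old fat. The region of 3 fragments on chromosome 2 between 203533528 and 203536444 rose from -1.36 ± 0.28 to 0.02 ± 0.23. The other regions that lost methylation, with 3 fragments each, lay on chromosome 12 between 43502823 and 43504777 (mean difference 0.92), on chromosome 4 between 155661038 and 155662566 (0.78) and on chromosome 10 between 72669116 and 72671451 (0.78). The region that gained methylation lay on chromosome 13 between 46634140 and 46635769 (-0.86). The count of 6 regions was 0 with loess, with the serial-number series as a block, within the one series that holds both ages of liver, and within date A or date B. It was 2 with date as a block, 585 in the value table and 310 with array weights. It was 3 without young liver 1 or 6, 2 without young liver 3, young liver 4 or old liver 1, 1 without old liver 4 or 5, and 10 without young fat 1. Across 8425 pairs of neighbouring fragments at most 300 bp apart, the liver age differences were correlated at r = 0.65, and at 0.42 after quantile normalization, although such pairs are not independent replicates.

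Date as a block gave 235 liver fragments, 201 of them among the 354. Within date A 59 passed and within date B 0 (limma, 557 at unadjusted p under 0.05). All 354 fragments had the same sign in either date, but they were selected in a fit that includes these arrays. Shared signs here and with the series as a block are therefore not independent support. With the serial-number series as a block, where only 3 young and 2 old livers share a series, 0 passed (limma, 1308 at unadjusted p under 0.05), again with all 354 signs the same and a median size of 0.77 log2 units instead of 0.81. With loess within each array 0 passed (limma, 2063 at unadjusted p under 0.05, against 5597 without loess), and 279 of the 354 kept their sign at a median size of 0.19. Quantile normalization between arrays gave 462, 284 less and 178 more methylated, and 231 of the 354 were among them in the same direction. The value table gave 11111 fragments, 4766 less and 6345 more methylated, and array weights gave 7531, 2754 less and 4777 more. All 354 were among those of the value table and among those with array weights. The count was 218 without young liver 4, 196 without old liver 4, 211 without old liver 5 and 542 without young fat 1.

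In fat, no fragment passed between old and young animals (limma, smallest adjusted p = 0.391), and 1665 had an unadjusted p under 0.05. By chance alone a share of about 0.05 of the 23063 fragments would do so. This reference holds for every unadjusted count given here, and such counts are not read as signal. The fragment with the smallest p, on chromosome 1 from 42439788 to 42440188, had a mean log2 ratio of -2.29 ± 0.14 in young fat (SD, n = 4) and -1.05 ± 0.53 in old fat (SD, n = 3). At both this fragment and the next, HpaII was above background on 3 of 4 young fat arrays. On chromosome 5 from 60108324 to 60108974 the means were -1.73 ± 0.31 and -0.67 ± 0.25. On chromosome 8 from 53888171 to 53888301 they were 2.2 ± 0.16 and 1.24 ± 0.30. Of the 10 fragments with the smallest p, the other 7 had differences of 1.02 (chromosome 5, start 75828008), 0.79 (chromosome 11, start 42890936), 0.96 (chromosome 4, start 160831533), -1.09 (chromosome 8, start 54107597), 0.94 (chromosome 13, start 95881869), 0.96 (chromosome 10, start 62755541) and 1.05 (chromosome 3, start 75562471). All 10 had limma adjusted p-values between 0.391 and 0.401.

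In simulated data, age differences of 1 log2 unit were found in 57.5% of cases in fat and 85.5% in liver, and differences of 0.5 in 5.5% and 21.5%. The simulated noise was independent between fragments, with the same spread on all arrays. It leaves out differences shared across an array, so recovery in the real data may be lower. Within date D, the one date with both ages of fat, 0 fragments passed (limma, 550 at unadjusted p under 0.05), and with date as a block 0 passed (627). Both values rest on 1 old fat sample, old fat 1, against 2 young ones, so they say little. The value table gave 358 fragments, 156 less and 202 more methylated in old fat, and array weights gave 326 less and 206 more methylated. Leaving out old fat 2 gave 5 fragments, and the serial-number series as a block gave 2, with young fat 1 as the only young fat sample that enters.

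The age effect itself differed between fat and liver at 14 fragments (limma, adjusted p under 0.05, with 5273 at unadjusted p under 0.05). Chance is not excluded for this count, as 6 of 100 assignments of age within each tissue, the real one included, gave as many. On chromosome 14 from 19113845 to 19114345 liver gained methylation, as given above, while fat had means of -1.09 ± 0.14 in young (SD, n = 4) and -1.11 ± 0.26 in old animals (SD, n = 3), and the effects differed by 1.92 (SE 0.24, limma adjusted p = 0.00358). On chromosome 10 from 63935957 to 63936937 liver lost methylation while fat had means of 1.23 ± 0.36 and 1.19 ± 0.15 (difference of effects -2.0, SE 0.30, limma adjusted p = 0.0113). On chromosome 11 from 76472629 to 76473246 the effects differed by 1.41. A fragment of the chromosome 7 region, from 135713046 to 135713306, rose from -0.39 ± 0.26 to 1.25 ± 0.19 in liver against -1.04 ± 0.20 and -0.72 ± 0.17 in fat (difference of effects -1.32, limma adjusted p = 0.0473).

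The other named fragments had limma adjusted p-values between 0.0466 and 0.0473. The effects differed by 1.79 on chromosome 6 from 108810799, by 1.47 on chromosome 1 from 65246589 and by 1.28 on chromosome 1 from 137935043. They differed by -1.56 on chromosome 19 from 9663941, by -1.50 on chromosome 1 from 98615940 and by -1.47 on chromosome 2 from 218149283. No fragment passed with date as a block (1312 at unadjusted p under 0.05) or with loess (3992), and all 14 kept their sign in both. Their median size was 1.51 log2 units with date as a block and 0.57 with loess, against 1.44 without either. With date as a block the fat age effect rests on old fat 1 alone. The 14 were selected on these same arrays, so their shared signs are not independent support. The value table gave 9761 fragments and array weights 5612, the 14 among them in both, while leaving out single samples gave between 1 and 38. The count was 5 without young liver 1, 4 without young liver 3, 4, 5 or 6, 4 without old liver 1, 4 or 5, 5 without old liver 2, and 8 without old fat 2. It was 38 without young fat 1, 5 without young fat 2, 3 or 4, and 1 without old fat 1 or old fat 3.

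Between the tissues of young animals, 5562 fragments differed, 24.1% of those tested (limma, adjusted p under 0.05). Fat was less methylated at 2828 and liver at 2734. The largest differences were at fragments less methylated in liver. On chromosome 11 from 80263212 to 80263695 the log2 ratio was 1.84 ± 0.49 in young liver (SD, n = 6) and -2.93 ± 0.53 in young fat (SD, n = 4), a ratio 27.2-fold higher in liver (difference -4.77, SE 0.28, limma adjusted p = 3.67e-10). On chromosome 4 from 55972974 to 55973372 the ratio was 24.3-fold higher in liver (1.74 ± 0.36 against -2.86 ± 0.43). On chromosome 8 from 75447961 to 75448432 it was 21.1-fold higher, and on chromosome 1 from 42794558 to 42794898 it was 18.6-fold higher. At each of these 4 fragments HpaII was above background on 3 of 4 young fat arrays. On chromosome 4 from 104410001 to 104411221 the HpaII signal was not above background on any young fat array, and the ratio was at least 18.3-fold higher in liver (limma adjusted p = 3.84e-08).

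Of the fragments less methylated in fat, the one on chromosome 1 from 42300713 to 42301337 had a log2 ratio of 1.36 ± 0.28 in young fat and -1.51 ± 0.19 in young liver, a 7.32-fold higher ratio in fat (difference 2.87, SE 0.17, limma adjusted p = 4.06e-10). Differences in the same direction were 2.86 on chromosome 20 from 37693880 to 37694610, 2.69 on chromosome 3 from 44525573 to 44526046, 2.47 on chromosome 2 from 93531776 to 93532726 and 2.45 on chromosome 13 from 78300179 to 78300742. HpaII was above background on 2 of 6 young livers at the fragments on chromosomes 20, 3 and 2, and on 5 of 6 at that on chromosome 13. The median difference was 0.79 over fragments less methylated in fat and -0.92 over those less methylated in liver.

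The tissue differences formed 278 regions of neighbouring fragments, 126 less methylated in fat and 152 less methylated in liver. The longest spanned 16356 bp on chromosome 7, from 135710477 to 135726833, and held 20 fragments. Its mean log2 ratio was 1.04 ± 0.22 in young liver and 1.73 ± 0.06 in old liver, against -1.29 ± 0.43 in young fat and -1.13 ± 0.35 in old fat. The ratio was 5.03-fold higher in young liver than in young fat. The 4 fragments of the liver age region lie inside it. Of 32 fragments mapped between 135695984 and 135728123, 28 were less methylated in young liver than in young fat and 1 was less methylated in fat. Old liver was less methylated than young liver at 8 of the 32 and more methylated at 0.

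**Figure D3:**
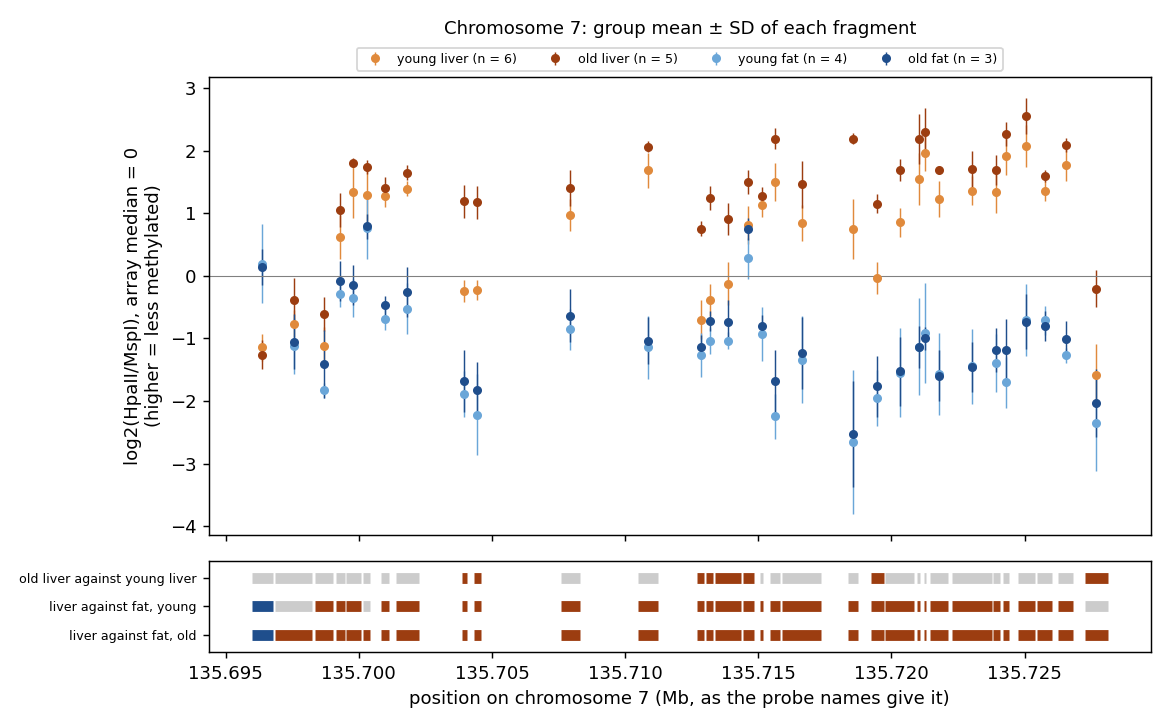
Upper panel, log2(HpaII/MspI) as group mean ± SD for each tested fragment along chromosome 7 (Mb) in the 4 groups. Lower panel, fragments less methylated (brown) or more methylated (blue) in the first-named group at limma adjusted p under 0.05 and others in grey, with 28 of 32 less methylated in young liver than in young fat.

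On chromosome 12, 10 fragments between 43521323 and 43527272 were less methylated in young liver, with means of 0.87 ± 0.20 against -0.71 ± 0.32 in young fat. On chromosome 10, 6 fragments between 87829441 and 87834814 had means of 1.01 ± 0.22 in young liver and -1.02 ± 0.18 in young fat. Another 6 between 72667162 and 72671451, which include the liver age region on chromosome 10, had means of 0.36 ± 0.16 and -1.29 ± 0.22. In the other direction, 7 fragments on chromosome 6 between 133965409 and 133973282 had means of 0.50 ± 0.17 in young fat and -0.40 ± 0.11 in young liver. On chromosome 1, 6 fragments between 82713032 and 82717433 had means of -0.31 ± 0.13 in young fat and -1.55 ± 0.44 in young liver. With date as a block 6412 fragments differed, 3446 of them among the 5562. Within date D 5641 differed, 2176 less methylated in fat and 3465 in liver, 3252 of them among the 5562. Loess gave 1975 fragments, 852 and 1123, and the serial-number series as a block, where young fat 1 is the only fat sample that enters, gave 1546, 425 and 1121. The value table gave 8554 and array weights 9748. The regions numbered 14 with loess, 50 with the series as a block, 425 in the value table and 595 with array weights.

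Between the tissues of old animals, 8444 fragments differed, 36.6% of those tested (limma, adjusted p under 0.05). Fat was less methylated at 4496 and liver at 3948. The fragment on chromosome 11 from 80263212 to 80263695 again had the largest difference, with 2.29 ± 0.17 in old liver (SD, n = 5) and -2.47 ± 0.73 in old fat (SD, n = 3), a ratio 27.1-fold higher in liver (difference -4.76, SE 0.32, limma adjusted p = 3.7e-09). On chromosome 7 from 135718362 to 135718732, inside the long region, the ratio was 26.3-fold higher in liver (2.19 ± 0.08 against -2.52 ± 0.85). Differences were -4.30 on chromosome 8 from 75447961 to 75448432, -4.16 on chromosome 4 from 55972974 to 55973372 and -4.13 on chromosome 1 from 42825545 to 42825735. HpaII was above background on 2 of 3 old fat arrays at these fragments, except the one on chromosome 7, where it was above background on all 3.

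Fat of old animals was less methylated on chromosome 20 from 37693880 to 37694610, with a log2 ratio of 0.98 ± 0.36 against -2.39 ± 0.37 in old liver, a 10.4-fold higher ratio (limma adjusted p = 1.37e-07), with HpaII above background on 3 of 5 old livers. Differences were 3.05 on chromosome 1 from 42280417 to 42280777, 3.01 on chromosome 1 from 157894311 to 157894941, 2.98 on chromosome 10 from 4799428 to 4800119 and 2.89 on chromosome 6 from 2530976 to 2531126. The longest of 515 regions was again on chromosome 7, from 135710477 to 135728123, with 21 fragments and a 6.98-fold higher mean ratio in liver. Of the fragments called in young animals, 4179 were also called in old animals, and 4163 of these had the same direction. Independent lists of these sizes would share 551 fragments less methylated in fat, where 2110 were shared, and 468 less methylated in liver, where 2053 were shared.

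No date held both tissues of old animals, so no value within a date can be given. With date as a block 1913 fragments differed, 1780 of them among the 8444, and 7737 of the 8444 kept their sign. That value rests on old fat 1 alone, which is linked to old liver only through young livers. The serial-number series as a block gave 2998, and loess gave 3179, of which 1321 were less methylated in fat and 1858 in liver. The value table gave 14184 and array weights 13667. Quantile normalization between arrays gave 7639 in old animals and 7755 in young animals. The larger count in old than in young animals was therefore not seen with one distribution on all arrays. The regions numbered 27 with loess, 65 with date as a block, 128 with the series as a block, 1015 in the value table, 964 with array weights and 333 without old fat 3. Leaving out single samples gave between 5764, without old fat 3, and 9657.

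For the share of tested fragments whose HpaII signal did not exceed background, no comparison of groups passed the test. It was 13.1% ± 9.47 in young liver (SD, n = 6), 7.40% ± 5.29 in old liver (SD, n = 5), 11.4% ± 16.5 in young fat (SD, n = 4) and 12.6% ± 10.1 in old fat (SD, n = 3). Two-sided exact permutation tests gave p = 0.266 for age in liver, p = 0.914 for age in fat, p = 0.833 for tissue in young and p = 0.411 for tissue in old animals. After Benjamini-Hochberg adjustment over the 4 comparisons these exact p-values lay between 0.821 and 0.914. The smallest p that the permutations can give is 0.00216, 0.0286, 0.00476 and 0.0179, in the same order. The differences were unstable in size and sign. Old minus young liver was -5.74 percentage points, but 0.05 without the 5 dim arrays and 6.77 for the share of fragments with a centred ratio below -1. Old minus young fat was 1.22, but 9.43 without young fat 1 and -4.5 without old fat 3. Young fat minus young liver was -1.76, but -9.97 without young fat 1 and 1.39 without young fat 4. Old fat minus old liver was 5.21, but -0.52 without old fat 3 and -10.2 for the share below -1. Within dates, old liver minus young liver was -2.08 percentage points in date A and -2.85 in date B. Young fat minus young liver was -14.3 in date D, and old fat minus young fat was 1.25 there, with 1 old sample.

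Across fragments, the age effect in liver and the age effect in fat were correlated at Pearson's r = -0.39 and Spearman's rho = -0.44. Fragments are not independent replicates, so the correlation was set against 99 random assignments of age within each tissue. Of these, 42 gave a correlation at least as far from 0, with values from -0.73 to 0.75. The correlation was -0.20 with date as a block, where the fat effect rests on old fat 1 alone. It was 0.12 after quantile normalization between arrays, 0.13 after the same step on the value table, and 0.09 without old fat 3. It was -0.23 after normexp, -0.16 without the 5 dim arrays, -0.57 without young fat 1 and -0.22 without young fat 3.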

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

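Quantile normalization, the value table, the serial-number series as a block and the splits of the samples for each count were planned. The tests of dim arrays, of dates, of splits by date or series of the value table normalized again and of random splits equalised on each side were chosen after the data were seen, as were random age labels for the correlation. The limits that decide on spread and on the overlap with the tissue comparison, apart from array date, were also set only after the results were seen.

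Single samples stood far from their group in 16 of 141 checks over 43 named fragments and 4 measures of each array, where chance sets apart about 1 in 20 groups. MspI signal exceeded background for 85.48% of fragments in old liver 2, against 90.84% to 92.63% in the other old livers, and for 74.41% in young fat 1, against 91.86% to 93.23%. Young fat 1 also had 36.02% of tested fragments with HpaII not above background, against 1.938% to 4.41% in the other young fat samples.

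Among fragments named for age in liver, young liver 2 had a log2 ratio of -0.6998 on chromosome 13 at 80220535, against -1.177 to -1.012 in the other young livers. Young liver 1 had 0.6838 on chromosome 2 at 2892808 (others 1 to 1.089) and 0.7039 on chromosome 1 at 42226795 (others 1.025 to 1.137), where old liver 5 had -0.8877 (others -0.2457 to -0.06248). Among those named for age in fat, old liver 1 had -2.26 on chromosome 5 at 75828008 (others -2.063 to -2.016) and old liver 2 had 1.98 on chromosome 8 at 54107597 (others 2.488 to 2.669).

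Among fragments named for the tissue comparisons, on chromosome 1 at 42300713 young liver 4 had -1.159 (others -1.648 to -1.483) and young fat 3 had 1.786 (others 1.199 to 1.243). Young liver 1 had 0.8941 on chromosome 11 at 80263212 (others 1.787 to 2.235) and 1.189 on chromosome 4 at 104410001 (others 1.585 to 1.761), where young fat 1 had -1.288 (others -3.389 to -3.356). Young fat 3 had -0.3158 on chromosome 1 at 157894311 (others -1.144 to -1.068), and old liver 2 had 2.342 on chromosome 7 at 135718362 (others 2.151 to 2.169). Of these 13 values at single fragments, 4 were from young liver 1, an array with MspI above background for 66.1% of fragments.

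The age effect differed between fat and liver at 14 fragments, by the test of the difference itself. Chance cannot be excluded for this count: 6 of 100 assignments of age within each tissue, the real one included, gave as many, and the highest other gave 4647.

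For age in liver, 2 of 100 splits of the 11 livers, the real one included, gave at least the real 354 fragments. These 100 were drawn from 462 possible splits, and the share lies under the 0.05 level. The livers fall into dates and series and are not exchangeable, so chance given that structure is not excluded. The other split gave 2177, several times the real count, which points to a structure among the livers. It set young livers 1 to 4 and old liver 2 (mean SD of the log2 ratios 1.36) against the rest (1.69). It is 1 array away from the split of date A against the other dates, which gave 492 fragments, more than the real split. The real split had a like contrast in spread, with a mean SD of 1.40 in young and 1.70 in old livers. Its count is thus not free of unequal spread. With one distribution on all arrays the real split gave 462, and 231 of the 354 were among them. With date as a block the real comparison gave 235, within date A 59 and within date B 0. Splits by serial-number series E and by series B, which holds old livers 3 to 5 and no other array, gave 0 each.

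For tissue in young animals 1 of 100 splits, the real one, gave 5562 or more, and the highest other gave 3754. That other split set young livers 2, 3, 5 and 6 against all other young arrays, so the fat arrays stayed together in it. The arrays fall into dates and series and are not exchangeable, so chance given that structure is not excluded. In old animals 1 of 56 splits, the real one, gave 8444 and no other gave a fragment (highest 0). No date held both tissues there, so the splits cannot separate tissue from date. For age in fat the real count was 0, so all 35 of 35 splits gave at least as many. The highest, 2268, set young fat 1, old fat 2 and old fat 3 against the other fat samples.

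For age in liver 11111 fragments differed in the value table, against 354 from the scanner ratios. The count fell to 545 once the table was quantile normalized over all 18 arrays. That step removes any difference in distribution, whatever made it. The fall alone therefore cannot separate the within-group equalisation that the table shows from another background step or probe summary. Random splits of the 11 livers, each side equalised by itself, gave a median of 0 fragments (4 of 50 above 354, highest 6032). The scanner ratios of the real groups treated so gave 8916. Within-group equalisation can thus raise the count without another background step or probe summary. What stays open is why the groups differed in distribution before equalisation, with age itself untested.

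Age effects in liver and fat were correlated at r = -0.39, and the sign reversed to 0.1215 when all arrays were given one distribution. Liver effects followed the young liver level (r = 0.77) and fat effects opposed the young fat level (r = -0.69), and neither relation held after that step (-0.01 and 0.01), so unequal spread of the arrays may account for the correlation. Without the 5 dim arrays r was -0.1579, between the values set for and against them. Opposite age changes in the 2 tissues cannot be told apart from chance labels, as 42 of 99 gave a correlation as far from 0, and quantile normalization would also remove a real change in spread.

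Of the 231 fragments less methylated in old liver, 121 (52.4%) were less methylated in young liver than in young fat, against 27.4 for independent lists. The 123 more methylated shared 30 with fragments less methylated in young liver than in young fat (14.6 for independent lists). They shared 29 with those less methylated in young fat (15.1). In simulations with no effect and the same shared young livers these 2 overlaps were 69.98 and 1.92 on average. The 30 on its own therefore cannot be read as an excess. The 29 lay above both references, so some excess was not specific to loss. For the 121, shared young livers favour the opposite direction and are argued against as the source, since simulations with no effect shared 3.62 on average (highest 8). With the young livers split this overlap was 4.584 and 5.258 times that of independent lists. It was 3.399 times with one distribution on all arrays and 3.268 times with date as a block, which argues against spread and date as its whole source. A larger share of liver cells in old liver was not settled by the limits set for it. The reference was fragments of the same level without a tissue difference. Against it, the median excess age change was 0.00473 over 4008 fragments less methylated in liver than in fat (quartiles -0.116 and 0.163, 51.1% above 0). Over 4790 less methylated in fat it was -0.0204 (-0.134 and 0.0927, 45.6% above 0). Neither median reached a shift of 0.1. The quartiles, which show the spread across fragments and not the error of the median, reach past it. A smaller or uneven shift cannot be told apart from none. An earlier, less specific test gave -0.0127 and -0.0154. Also open are the serial-number series, not tested here since no fragment passed for age with it as a block, and age itself, as a hypothesis found on the same data.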

How the results depend on the processing

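Date as a block, comparisons within a date, leaving out the 5 dim arrays, the MspI filter on the compared groups and the value table quantile normalized again were chosen after seeing the data. Unless said otherwise, the cause of a change was not tested.

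Named fragments are the most extreme of each comparison, so their calls say little about the others. Named tissue fragments of young animals kept their direction and call in 359 of 360 values under alternatives, and those of old animals in 348 of 349, with loess the exception in both. Named liver age fragments kept their direction in all 380 values and their call in 336. The call ended for all 10 with loess, with the serial-number series as a block or as the only series, and within date B, where fewer arrays enter. It ended for 4 with the replicate block. Named fat fragments stayed short of the threshold in 342 of 358 values, and interaction fragments kept their call in 140 of 329. None reversed.

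Loess gave 0 fragments for age in liver, 1975 for tissue in young animals, 3179 for tissue in old animals and 0 for the interaction. In the same order, and with age in fat second, the value table gave 11111, 358, 8554, 14184 and 9761, array weights gave 7531, 5.3e+02 (326 less and 206 more methylated in old fat), 9748, 13667 and 5612, and the serial-number series as a block gave 0, 2, 1546, 2998 and 0. Livers of only one series gave 0 for age. A log2 difference of at least 1 left 94 for age in liver, 2017 for tissue in young and 3527 for tissue in old animals. Date as a block gave 235 for age in liver, 1913 for tissue in old animals and 0 for the interaction, and age in liver gave 59 within date A and 0 within date B. The value table quantile normalized again gave 545 for age in liver and 134 for the interaction.

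The interaction count was 90 after quantile normalization, 9 with length bins, 63 after normexp, 3 with the median of probes, 0 with no MspI filter, 28 with MspI above background on all arrays, 50 with trended and robust eBayes, and 0 without the 5 dim arrays. Without an MspI filter 299 fragments were less and 20 more methylated in old liver.

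Leaving out 1 sample gave 196 (without old liver 4) to 542 (without young fat 1) fragments for age in liver, 0 to 5 (without old fat 2) for age in fat, 4618 to 6869 for tissue in young animals, 5764 to 9657 for tissue in old animals and 1 to 38 for the interaction. The correlation of age effects ran from -0.5739 (without young fat 1) to 0.09036 (without old fat 3), which reversed it. It was also reversed by quantile normalization of the ratios (0.1215) and of the value table (0.1305). It was -0.2336 after normexp and -0.1579 without the 5 dim arrays. The differences in the share of fragments with HpaII not above background changed in size and sign, as given above. None had an unadjusted exact p under 0.05, with 1 exception. A share below a centred ratio of -1 differed by -10.2 points between tissues of old animals (exact p = 0.0357, not adjusted over the comparisons).

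With the replicate number as a block, 21 fragments passed for age in liver, 5617 for tissue in old animals and 0 for the interaction, and the regions numbered 0 for age in liver, 173 for tissue in young and 310 for tissue in old animals. Deviations of same-numbered samples correlated from -0.61 to 0.31 between ages in liver, -0.67 to 0.36 between ages in fat, -0.32 to 0.69 between tissues in young (median 0.21, others -0.003) and -0.50 to -0.10 in old animals. As not every pair was above 0.1, the numbers are taken as a label only, though the labels do not say whether liver and fat come from the same animals. Signal over background limits the dim arrays, where 61.1% to 74.4% of fragments had MspI above background. The gene list tests and their alternatives were not run, and the interaction already uses all arrays, so an own-arrays fit gives no separate value.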

Other observations

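The windows, group levels and counts by chromosome and length given here were all chosen after the calls were seen.

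Of the 354 liver age differences 19 lay in the 6 regions, and a few windows held several others close together. Of 2536 windows of 500000 bp, the one with the most called fragments, 10 of 80, lay on chromosome 7 between 135653643 and 135971241, and all 10 were less methylated in old liver. In 9 of 1000 random placements of the calls a window held as many, although such placements ignore the correlation of neighbours, and no other window was set against chance. The next window, on chromosome 4 between 155520386 and 155696808, held 9 of 36 fragments, again all less methylated in old liver. Adjacent windows on chromosome 12 went opposite ways. Between 43009063 and 43497481, 4 of 92 fragments were more methylated in old liver and 0 less, and 21 were less methylated in young fat than in young liver against 3 in the other direction. Between 43502479 and 43930742, 3 of 52 were less methylated in old liver and 0 more, and 19 were less methylated in young liver than in young fat against 1.

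In some windows more tissue differences went one way than the other, which was not tested. On chromosome 19 between 22560748 and 22916385, 15 of 29 fragments were less methylated in young liver than in young fat and 0 the other way. On chromosome 10 between 56501313 and 57000115, 35 of 164 were less methylated in young fat and 10 in young liver. On chromosome 1, 25 of 74 fragments between 42111728 and 42453115 were less methylated in young fat and 9 in young liver, while between 42677088 and 42865616 the counts were 2 and 19 of 59. Chromosome X had the lowest share of tissue calls, with 16.7% of 222 fragments in young and 24.3% in old animals, and also ranked lowest after quantile normalization (24.3% in young animals).

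The 231 fragments less methylated in old liver had median log2 ratios of 0.15 in young liver, 1.14 in old liver, -0.63 in young fat and -0.43 in old fat. Old fat lay above young fat at 162 of them (70.1%), against 50% of all fragments, and at 135 after quantile normalization. The 123 fragments more methylated in old liver had medians of -0.32, -1.11, -0.43 and -0.33 in the same order. Old fat lay below young fat at 39 of these (31.7%), and at 53 after quantile normalization. No test was run on these fat values, and no fragments of like level were used as a reference. Both sets lay low in young fat, and over all fragments fat age effects opposed the young fat level (r = -0.69). That relation was gone after quantile normalization (0.01), so unequal spread of the arrays may account for these shares.

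In old animals the direction of tissue calls differed between classes of fragment length, which was not tested. Among the shortest fragments, with a last probe at 271 bp or less, 9.83% were less methylated in fat and 17.1% in liver. Among the longest, beyond 816 bp, 25.6% were less methylated in fat and 13.7% in liver. In young animals the shares were 9.59% and 8.04% among the shortest and 14.8% and 12% among the longest. The SD of the log2 ratios across fragments was 1.40 ± 0.26 in young liver, 1.70 ± 0.16 in old liver, 1.49 ± 0.25 in young fat and 1.29 ± 0.30 in old fat. Median ratios ran from 1.17 in the shortest class to -0.95 in the longest in old liver. In old fat they ran from 0.82 to -0.60. Unequal spread of the arrays may account for the directions in old animals, which was not tested.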
